A study of Mus musculus with 4 samples.

How the data were processed

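Total RNA was taken from adult neural stem cells of 8-week-old C57BL/6 mice, per the labels' protocols, after infection with a lentivirus that carried either a scrambled short hairpin RNA (ctrl, 2 libraries) or a short hairpin RNA against Ogt (shOGT, 2 libraries). A short hairpin RNA is processed in the cell into a small RNA that lowers the transcripts it pairs with. RNA integrity was measured before library preparation, per the labels' protocols, and its values are not given in the sources used here. Groups were taken from the labels' treatment field and replicate numbers from the sample titles. The labels do not say whether the 2 libraries of a group came from separate cultures. The p-values of single genes thus measure only the spread between these samples, which may be technical. No p-value here can be taken to measure the spread between cultures.

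The deposited files give 1 signal value per gene and library for 25261 Ensembl gene identifiers. The submitters' processing notes name the genome build mm10; the aligner, the counting tool, the annotation and the normalization method are not given in the sources used here, nor is it stated whether counting used strand. Within each library every deposited signal value was a whole multiple of a single step, which was 0.997 in ctrl 1, 0.992 in ctrl 2, 1.06 in shOGT 1 and 0.943 in shOGT 2. A whole multiple was accepted within 0.01 of a step, and 100% of the values met this. Values of this form arise when reads counted per gene are divided by 1 factor per library. Taken as such, the libraries held 16909316, 17090949, 15697508 and 17753976 reads assigned to genes (ctrl 1, ctrl 2, shOGT 1, shOGT 2). No test that models whole read counts was run on them, and the values were used as deposited. Gene symbols and positions came from GENCODE M21 on GRCm38, the assembly that mm10 names; 25242 of the identifiers matched and 19 did not. Where exons of a named gene overlap those of another gene, reads may have been counted for either gene.

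Before any comparison, replicates were checked. A chi-square was taken over genes with at least 20 implied reads summed over the 2 libraries compared. It gave 2.04 per gene between the ctrl libraries and 3.34 between the shOGT libraries, where sampling noise alone gives 1. The replicates of each group thus differed by more than sampling noise, and each was counted as a separate sample. Between groups the same measure was 7.51 to 8.17 per gene.

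The comparison of shOGT with ctrl used limma 3.58.1 in R 4.3.3, with an empirical Bayes fit that lets the variance follow a trend in expression. It was run on log2(value + 1) for the 21829 genes with a value of at least 1 in at least 2 of the 4 libraries. Fold changes are therefore on the log2(value + 1) scale, which understates the change of low genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called higher or lower. The test, its filter and the gene lists were fixed before the data were examined; the branch for normalized values was used, although it had been written for other normalized units. The rule for named genes took Ogt, then the 12 called genes with the largest log2 fold change in each direction, provided that both shOGT values lay on the same side of both ctrl values and the mean reached 5 CPM, computed from the deposited values. Symbols of clones, predicted models and pseudogenes were left out. The minimum of 5 CPM had been written for count tables and was kept because the values behave like counts. The rule also named up to 4 members of each list with the smallest unadjusted p, and any member of the 2 Notch lists.

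Gene lists were tested with camera, 2-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over all 37 lists. With the preset correlation its p compares the members with other genes and rests on the number of genes. Such a p can be very small with 4 libraries and does not measure replication. Each list was also tested with the correlation estimated from the data, and with fry. The directional p of fry asks whether the genes of a list move one way on balance, without comparing them with other genes. The estimated correlation rests on these 4 libraries alone, so that camera with it had little power over 37 lists. Its unadjusted p for the ribosomal protein list was 0.025, where the preset correlation gave an adjusted p of 1.7e-14. A list that did not pass it is therefore not shown to be unchanged. No other correlation across samples was computed. An exact permutation test of 2 against 2 libraries cannot reach 0.05, so that single values carry limma's model-based p. Other splits of the samples were not counted, since groups held fewer than 3 libraries.

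The tests were checked on simulated data for this comparison, with reads drawn for 21870 genes from the means of the real libraries and 200 genes of mean at least 100 changed. At a log2 fold change of 0.3, 55.2% of the changed genes were recovered; at 0.5, 92.5%; at 1, 100%. There were 0 false calls among 165 calls, and 0 calls when no gene was changed. In a simulation over 21819 genes, a list of 30 genes lowered by 0.15 on the log2 scale was found, and 0 other lists passed. Those other lists were random sets of genes that varied independently, so that false calls of lists with correlated members were not checked. Genes of similar level shared 1 spread, set at a median, so that a spread that differs from gene to gene was not simulated. The recovered shares and the 0 false calls hold for that case, and the real test may do worse. That spread was also the same in both groups, whereas the real replicates differed more in shOGT (3.34 per gene) than in ctrl (2.04).

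The alternatives covered quantile normalization, no filter, a minimum of 5, a pseudocount of 0.1, the replicate number as a block, a fit without the variance trend, stricter thresholds, and leaving out each library in turn. After the data had been seen, a minimum of 10, rescaling to equal library totals, and combinations of the minimum of 10 with other settings were added. For the sequence tests of the closing section, the longest annotated 3' UTR per protein-coding gene was taken from GENCODE M21. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used there, and matplotlib 3.10.9 for the plots.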

Results

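The series measured gene expression by RNA sequencing in mouse adult neural stem cells, the dividing cells of the adult brain that give rise to neurons and glia. Ogt encodes O-GlcNAc transferase, which attaches single N-acetylglucosamine sugars to nuclear and cytoplasmic proteins. Cells with a hairpin RNA against Ogt (shOGT, n = 2) were compared with cells that carried a scrambled hairpin (ctrl, n = 2), and the series title ties Ogt to adult neurogenesis and to Notch signalling. Values are the deposited signal per gene. The step between values implies 16909316 and 17090949 reads assigned to genes in ctrl and 15697508 and 17753976 in shOGT, and 22607 to 22931 genes had a value above 0. Mitochondrial transcripts took 3.45% and 3.39% of the total in ctrl and 3.58% and 3.63% in shOGT.

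Ogt itself was lower in both shOGT libraries, at 3379 and 3516, than in both ctrl libraries, at 4112 and 4138. Its mean fell by 16.4%, from 4125 ± 18.2 to 3447 ± 97.1 (SD, n = 2 each), a log2 fold change of -0.26 ± 0.04 (SE; limma adjusted p = 0.00876). Ogt (ENSMUSG00000034160) is a protein-coding gene on the plus strand of chromosome X, at 101640060 to 101684351 on GRCm38. Mgea5, the gene of O-GlcNAcase, which removes the sugar that Ogt attaches, fell as well, from 3199 ± 8.55 to 2571 ± 29.5 (log2 fold change -0.32 ± 0.04, adjusted p = 0.00373). These were the 2 called members among 20 tested genes of O-GlcNAc cycling and hexosamine synthesis, and 3 were lower when adjusted over the list alone. The list as a whole did not pass camera (adjusted p = 0.347), with a median of -0.04 that was 0.02 without shOGT 2. The 3' UTR of Mgea5 held GCTATC, and that of Ogt held neither GCTATC nor GTACCC. Without ctrl 1, ctrl 2, shOGT 1 or shOGT 2 the log2 fold change of Ogt was -0.26, -0.25, -0.23 and -0.29, and its adjusted p was 0.331, 0.325, 0.308 and 0.297.

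Across the transcriptome the changes were many and small. Of 21829 genes tested, 427 were higher and 633 lower in shOGT, with a median absolute log2 fold change of 0.33. The median fold among the called genes was 1.26 for those higher and 0.796 for those lower, and 38 called genes reached an absolute log2 fold change of 1, 22 of them higher. In 49.3% of the tested genes both shOGT values lay on one side of both ctrl values, where chance gives 33.3%. Higher genes made up 40.3% of the calls, and 50.3% (593 higher, 585 lower) once the libraries were rescaled to equal totals. Leaving out ctrl 1, ctrl 2, shOGT 1 or shOGT 2 left 0 genes past the threshold in limma, with 2484, 2555, 3300 and 3389 genes at an unadjusted p under 0.05. Quantile normalization, no filter and a fit without the variance trend also gave 0 calls, with 3998, 4302 and 2763 such genes. At a minimum of 10, chosen after the data had been seen, quantile normalization gave 1657 calls and the fit without the trend 0.

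**Figure D1:**
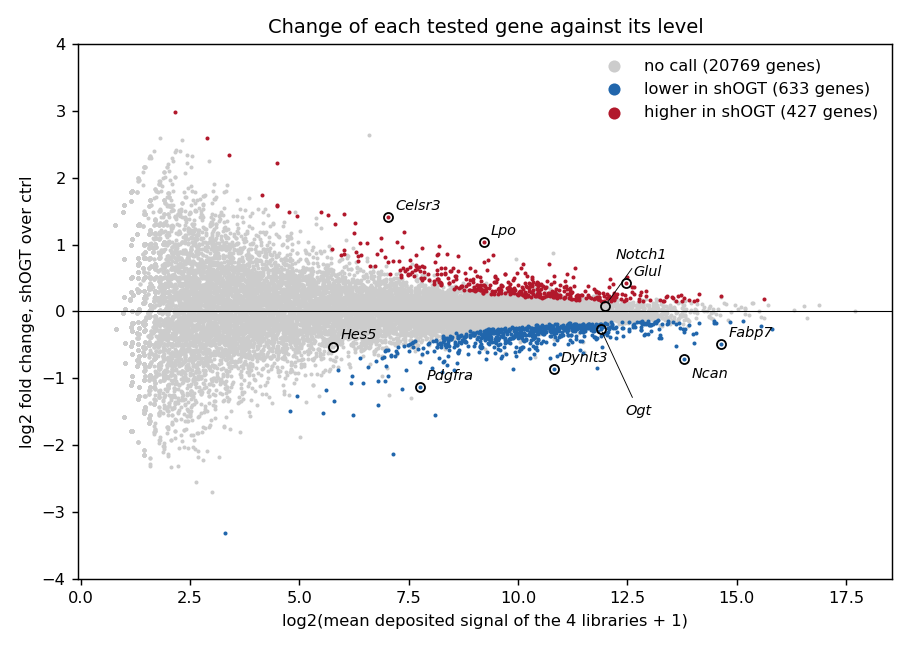
Log2 fold change of shOGT over ctrl (y axis) against the log2 of the mean deposited signal of the 4 libraries plus 1 (x axis), 1 point per tested gene; the 427 genes called higher are red, the 633 called lower are blue and circled genes are named. Ogt lies at -0.26, Ncan at -0.71, Celsr3 at 1.41 and Pdgfra at -1.13.

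Among the genes of at least 5 CPM that the naming rule took, the largest rise was that of Celsr3, a cadherin needed for the growth of axon tracts, from 70.1 ± 5.19 to 188 ± 18.1 (SD, n = 2; log2 fold change 1.41 ± 0.15, adjusted p = 0.00172). Further rises were those of Htr1b, a serotonin receptor (1.10), Ptpn5, a neuronal phosphatase (0.97), Celf4, a neuronal RNA-binding protein (0.92), Chrnb2, a nicotinic acetylcholine receptor subunit (0.87), and Ap3b2, a neuronal adaptor subunit (0.86). Klhdc7a rose by 1.19, Ckmt1, a mitochondrial creatine kinase, by 1.04, and Lpo, lactoperoxidase, by 1.04. Gdap1 (1.02), Cybrd1 (0.98) and Cemip, a hyaluronan-binding protein (0.86), completed the 12. Exons of Htr1b, Ckmt1 and Chrnb2 overlap those of D430036J16Rik, Strc and Adar, so that reads of these pairs could not be told apart without strand. The 3' UTRs of Ptpn5, Chrnb2 and Cemip held the sequence GTGTCAC, found in 20.9% of the higher genes and 11.4% of the expressed genes with a 3' UTR, and 4 of the 12 (Klhdc7a, Gdap1, Cybrd1 and Chrnb2) held GCTATC or GTACCC.

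The 12 largest falls under the same rule included Pdgfra, the receptor that marks oligodendrocyte progenitors, from 295 ± 10.8 to 134 ± 3.43 (log2 fold change -1.13 ± 0.11, adjusted p = 0.0013), and Gpr17, a receptor of committed oligodendrocyte precursors (-0.88). Sema3c, a secreted guidance cue (-1.05), Sfrp2, a secreted modulator of Wnt signalling (-0.97), and the collagen gene Col12a1 (-0.85) fell as well. So did Cd36, a fatty acid receptor (-1.04), Phf8, a histone demethylase (-0.91), St6galnac3, a sialyltransferase (-1.08), Kctd13 (-0.87), Wbp1 (-0.86) and Dynlt3, a dynein light chain (-0.86). Srp54b (-1.55; -0.99 without shOGT 1) is uncertain, since near-identical copies of this gene can share its reads, and exons of Gpr17 overlap Lims2 and those of Kctd13 overlap Asphd1. Of these 12 genes, 7 (Pdgfra, St6galnac3, Sema3c, Cd36, Gpr17, Kctd13 and Dynlt3) held the sequence GCTATC or GTACCC in the 3' UTR, as did 55.5% of the lower genes and 31.1% of the expressed genes.

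The series title raises the question whether Notch signalling differs with Ogt, and in these libraries most Notch genes did not pass the test. Of 46 tested receptors, ligands and processing factors, 0 were higher and 2 lower: Neurl1b, a ubiquitin ligase of Notch ligands (-0.46 ± 0.06, adjusted p = 0.0046), and Adam17, a protease that can cleave Notch (-0.18 ± 0.04, adjusted p = 0.0483). Adjusted over the list alone, 1 was lower. The 3' UTRs of Neurl1b and Adam17 held GCTATC or GTACCC, and exons of Adam17 overlap Iah1. Notch1 measured 3949 ± 87.1 in ctrl and 4182 ± 102 in shOGT (0.08 ± 0.04, adjusted p = 0.302), Notch2 0.28 ± 0.10, Notch3 -0.10 ± 0.06, Dll1 0.17 ± 0.08 and Jag1 0.22 ± 0.10. Rbpj, the DNA-binding partner of cleaved Notch, measured 0.19 ± 0.05 (adjusted p = 0.0781). The list had a median of -0.002, a mean of 0.002 and camera's direction was up (adjusted p = 0.729), so that median and mean differed in sign; the median was 0.01 with quantile normalization and with libraries rescaled to equal totals, 0.03 without ctrl 2, 0.02 without shOGT 2 and -0.02 without shOGT 1.

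Of 19 tested Notch target genes, 1 fell: Fabp7, a fatty acid binding protein of radial glia and stem cells, from 29997 ± 642 to 21426 ± 1427 (-0.49 ± 0.04, adjusted p = 0.000971). Adjusted over the list alone, the count was also 1. The canonical effector Hes5 measured 75.8 and 52.6 in ctrl and 44.7 and 42.4 in shOGT, a log2 fold change of -0.53 with a 95% interval of -1.06 to 0.01 (adjusted p = 0.264; -0.27 without ctrl 1). Hes1 measured 0.17 ± 0.08 (adjusted p = 0.31), Hey1 0.03 ± 0.08, Nrarp, whose 3' UTR held GTACCC, -0.22 ± 0.13 and Gfap 0.33 ± 0.14, which was 0.05 without shOGT 2 and 0.62 without shOGT 1. The median of the list was -0.02 and camera did not call it (adjusted p = 0.272; adjusted p = 0.556 with an estimated correlation), while the directional p of fry, adjusted, was 0.0447. Without ctrl 2 the median was 0.003, without shOGT 1 it was -0.06 and without shOGT 2 it was -0.01. With libraries rescaled to equal totals the median was -0.006, and at a minimum of 5 or of 10 it was -0.04.

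**Figure D2:**
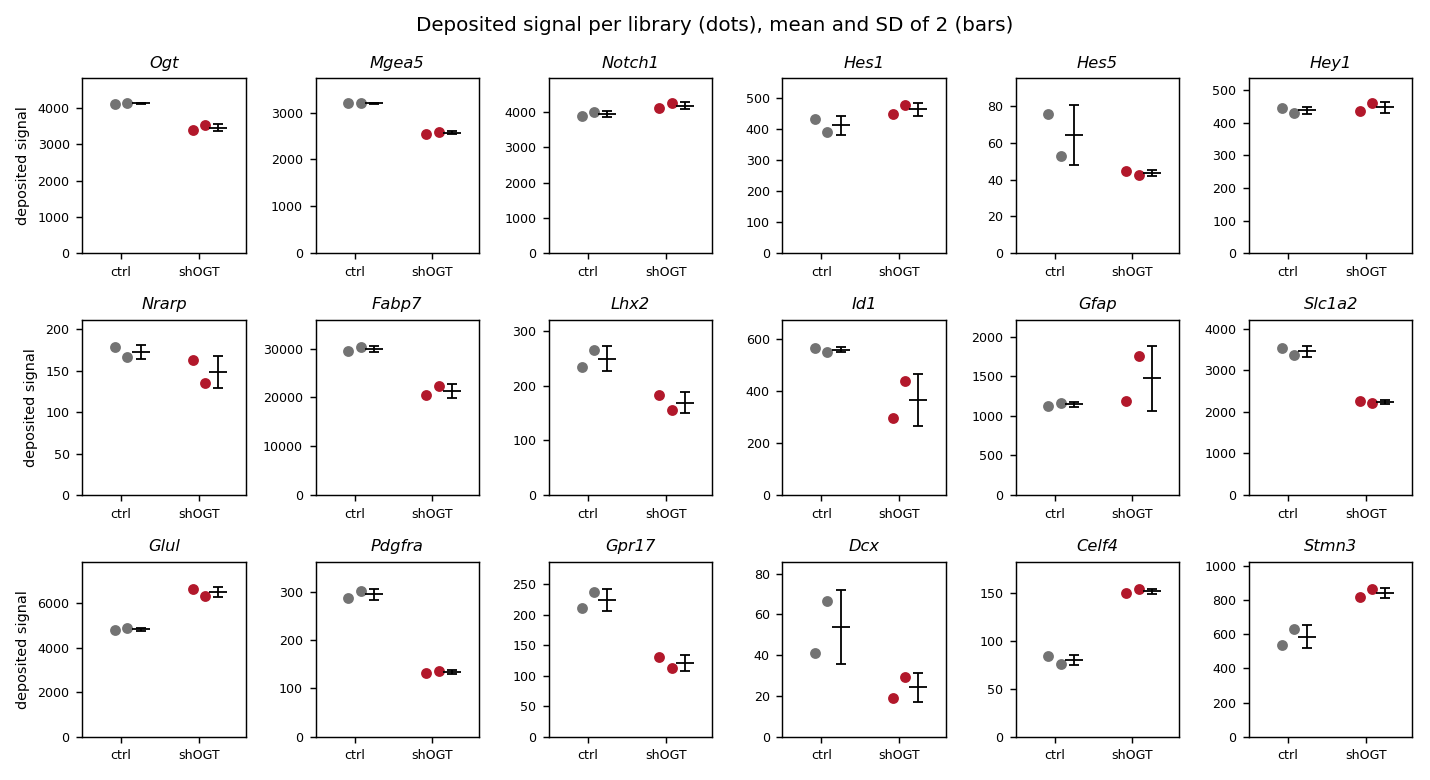
Deposited signal per library (y axis, from 0) of 18 named genes in ctrl (grey) and shOGT (red); each dot is 1 library and the bars show the mean and SD of 2. Ogt, Fabp7, Slc1a2 and Pdgfra are separated between the groups by more than their spread, whereas Hes5, Gfap and Dcx vary between the libraries of a group.

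Among the genes of neural stem cell identity, 5 of 33 fell and 0 rose. They included Lhx2 (-0.56 ± 0.12, adjusted p = 0.0339) and Id1, an inhibitor of differentiation downstream of BMP (-0.64 ± 0.15, adjusted p = 0.0442; -0.35 without shOGT 1), besides Fabp7. Adjusted over the list alone, 3 were higher and 10 lower. The list had a median of -0.08 and missed the threshold in camera (adjusted p = 0.0505). Without shOGT 1 the median was -0.02 (adjusted p = 0.277) and without shOGT 2 it was -0.11 (adjusted p = 0.0462), and the list passed at a minimum of 5 (0.0456). Of the proneural and neuroblast genes, 2 of 31 were higher and 1 lower, the same counts as adjusted over the list alone, with Stmn3 at 0.52 ± 0.08 and Stmn1 at -0.20 ± 0.04 (adjusted p for the list 0.517, with a median of 0.0005 that was -0.02 with quantile normalization, -0.04 without ctrl 2, 0.13 without ctrl 1, 0.06 without shOGT 1 and 0.14 without shOGT 2). Dcx, a marker of young neurons, measured 53.7 ± 18.1 in ctrl and 24.2 ± 7.13 in shOGT and did not pass (adjusted p = 0.0894). Of the genes of mature neurons and synapses, 2 of 40 rose, among them Map2 (0.15), and 2 fell (Nlgn3 -0.39, Homer1 -0.36; adjusted p for the list 0.835), with 6 higher and 4 lower adjusted over the list alone. Homer1, Nlgn3, Map2, Stmn3 and Dcx held GCTATC or GTACCC in the 3' UTR.

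Glial genes moved in both directions. Of 30 tested astrocyte genes, 5 rose and 5 fell: Glul, glutamine synthetase, rose from 4834 ± 68.3 to 6496 ± 235 (0.43 ± 0.04, adjusted p = 0.00114), and Slc1a2, a glutamate transporter, fell from 3460 ± 131 to 2240 ± 43.4 (-0.63 ± 0.05, adjusted p = 0.00053). The list did not pass (adjusted p = 0.136), with 6 higher and 10 lower adjusted over the list alone. The 3' UTR of Slc1a2 held GCTATC and GTACCC several times, and those of Slc1a2 and Glul held GTGTCAC. Of 32 oligodendrocyte lineage genes, 4 fell and 0 rose, among them Pdgfra, Gpr17, Lhfpl3 (-0.26) and Cntn1 (-0.20), while the list missed the threshold (adjusted p = 0.0865). Adjusted over the list alone, 2 were higher and 4 lower.

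Of 66 tested genes of G2/M and mitosis, 17 fell and 0 rose (41 lower adjusted over the list alone), with a median of -0.16 and a camera adjusted p of 4.7e-20. With an estimated correlation the list's adjusted p = 0.374, and that of fry was 0.0523. Examples were Ccnb1, cyclin B1 (-0.34 ± 0.04), Cdca3 (-0.33 ± 0.05), Birc5, survivin (-0.36 ± 0.06), and Kif11, a mitotic kinesin (-0.23 ± 0.04). Of 58 genes of G1/S and DNA replication, 4 fell (5 adjusted over the list alone): Pola1 (-0.32), Fen1 (-0.52), Usp1 (-0.18) and Pcna (-0.16). That list had a median of -0.06 (adjusted p = 0.00241; 0.556 as the adjusted p with an estimated correlation), and it did not pass without ctrl 2 (median -0.02, adjusted p = 0.0772) or shOGT 2 (-0.04, 0.102). Without ctrl 1 the median was -0.09. Of 20 CDK inhibitors and G1 regulators, 4 fell and 0 rose, namely the cyclin Ccnd3 and the inhibitors Cdkn2c, Cdkn2d and Cdkn2a (-0.47, -0.22, -0.33 and -0.30), with 1 higher and 6 lower adjusted over the list alone. That list's adjusted p = 0.026, and it was 0.374 with an estimated correlation, 0.148 without ctrl 2, 0.129 without shOGT 1, 0.102 without shOGT 2, 0.0533 with libraries rescaled to equal totals, 0.104 with quantile normalization and 0.0547 at a minimum of 10. Birc5, Fen1 and Ccnd3 held GCTATC or GTACCC in the 3' UTR. Among measures of RNA quality, the 13 mitochondrially encoded mRNAs had a median of 0.09 (0.006 without shOGT 2 and 0.14 without ctrl 1), the 77 ribosomal protein genes one of -0.10, and 0 of 38 replication-dependent histone genes were called, with a median of -0.40.

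Of 26 cholesterol synthesis genes, 15 fell and 0 rose, with a median of -0.25 (camera adjusted p = 8.6e-15; 0.374 as the adjusted p with an estimated correlation and 0.0755 by fry) and 2 higher and 21 lower adjusted over the list alone. Hmgcs1, which makes HMG-CoA, fell from 19060 ± 303 to 15167 ± 742 (-0.33 ± 0.04, adjusted p = 0.00262), and Msmo1 (-0.38), Mvk, mevalonate kinase (-0.41), and Cyp51 (-0.34) fell as well. In fatty acid and lipid synthesis 7 of 26 genes fell and 0 rose, among them the desaturases Scd1 (-0.36) and Scd2 (-0.26), Elovl6 (-0.35) and Acly (-0.24). That list had a median of -0.09 (adjusted p = 4.5e-05; 0.374 as the adjusted p with an estimated correlation and 0.0577 by fry), with 1 higher and 11 lower adjusted over the list alone. Msmo1, Scd1, Scd2 and Elovl6 held GCTATC or GTACCC in the 3' UTR, Elovl6 held GTGTCAC too, and exons of Cyp51 overlap Akap9.

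Ldha, lactate dehydrogenase A (-0.30 ± 0.07, adjusted p = 0.0426), and Tpi1 (-0.33 ± 0.08, adjusted p = 0.0454) were the 2 of 23 glycolysis genes that fell, and 3 were lower adjusted over the list alone. Ddit4 (-0.36) and P4ha1 (-0.48) were the 2 of 29 hypoxia genes that fell, with 3 adjusted over the list alone. Without shOGT 2 the values of Ldha, Tpi1 and P4ha1 were -0.17, -0.20 and -0.31. The medians were -0.12 and -0.33 (camera adjusted p = 0.00879 and 0.000753; 0.569 as the adjusted p of both with an estimated correlation, and 0.504 and 0.487 by fry). Without shOGT 2 they were -0.04 and -0.09, with adjusted p of 0.741 and 0.281, and without ctrl 1 the adjusted p was 0.0744 and 0.143. The glycolysis median was -0.07 without ctrl 1, -0.18 without ctrl 2 and -0.24 without shOGT 1. For glycolysis the call was also lost with quantile normalization (adjusted p = 0.136) and without a filter (0.0552). Tpi1 and Ddit4 held GCTATC or GTACCC in the 3' UTR, and Tpi1 held GTGTCAC too.

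Of 46 genes of the integrated stress response and unfolded protein response, 9 fell and 1 rose (14 and 2 adjusted over the list alone). The endoplasmic reticulum factors Edem1 (-0.53), Pdia6 (-0.30) and Hsp90b1 (-0.26) fell and Slc3a2, an amino acid transporter subunit, rose (0.28). The median was -0.12 (adjusted p = 0.000724; 0.374 as the adjusted p with an estimated correlation), and -0.06 without ctrl 2 (adjusted p = 0.0106). Of 28 oxidative stress and NRF2 genes, 5 rose, among them Gstm1 (0.48 ± 0.04), Nfe2l2, which encodes NRF2 (0.34 ± 0.05), and Ftl1 (0.25), and 3 fell, among them Sod1 (-0.37); 13 were higher and 4 lower adjusted over the list alone. The list passed (median 0.09, adjusted p = 0.0189; 0.374 as the adjusted p with an estimated correlation), but not without ctrl 2 (0.0512), shOGT 1 (0.0689) or shOGT 2 (0.0856). In p53 targets and apoptosis 5 of 39 rose and 1 fell (6 and 1 adjusted over the list alone). Zmat3 (0.65 ± 0.05), Trp53 itself (0.26) and Trp53inp1 (0.19) rose, and Phlda3 fell (-0.53). The list's median was 0.05 (adjusted p = 0.0097; 0.374 as the adjusted p with an estimated correlation), and its adjusted p was 0.0528 without ctrl 2 and 0.0548 without shOGT 1. Without shOGT 2 the median was 0.10. Edem1, Slc3a2 and Phlda3 held GCTATC or GTACCC in the 3' UTR, and Zmat3 held GTACCC and GTGTCAC.

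Of 48 tested interferon response genes, 3 rose, Gbp3 (0.63 ± 0.12), Gbp7 (0.49 ± 0.11) and Parp14 (0.75 ± 0.17), and 0 fell, with 6 higher and 1 lower adjusted over the list alone. The list's median was 0.20 (adjusted p = 0.000753; 0.374 as the adjusted p with an estimated correlation). The inflammatory NF-kB list did not pass (adjusted p = 0.0662), with Cebpd (0.31) the 1 higher of 27, and it passed without shOGT 1 (adjusted p = 0.0203); 3 were higher and 1 lower adjusted over the list alone.

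Of 77 ribosomal protein genes, 14 were lower and 0 higher (28 lower adjusted over the list alone), with Rpl13a (-0.61 ± 0.07), Rpl23a (-0.30), Rpl35 (-0.24) and Rps7 (-0.24). The list's adjusted p = 1.7e-14, and it was 0.374 with an estimated correlation. The 3' UTRs of Rpl13a, Atp5l and Atp5f1 held GCTATC or GTACCC. The mitochondrially encoded mRNAs were higher in 3 of 13 cases, mt-Nd2 (0.19 ± 0.03), mt-Nd6 (0.15) and mt-Atp8 (0.91), with 6 higher adjusted over the list alone. Exons of mt-Nd6 overlap mt-Nd5 and those of mt-Atp8 overlap mt-Atp6. Their list's adjusted p = 0.00264, with 0.449 as the adjusted p with an estimated correlation, 0.191 without ctrl 2, 0.102 without shOGT 2 and 0.124 with quantile normalization. The nuclear-encoded respiratory chain had 3 of 69 genes lower, Atp5l (-0.38), Cycs (-0.21) and Atp5f1 (-0.16), and did not pass with all 4 libraries (adjusted p = 0.0662) but passed without shOGT 1 (0.0385), with 2 lower adjusted over the list alone. The replication-dependent histone list passed (adjusted p = 0.0186; 0.374 as the adjusted p with an estimated correlation) with 0 genes called in limma or adjusted over the list alone, and did not pass without shOGT 2 (0.0856).

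**Figure D3:**
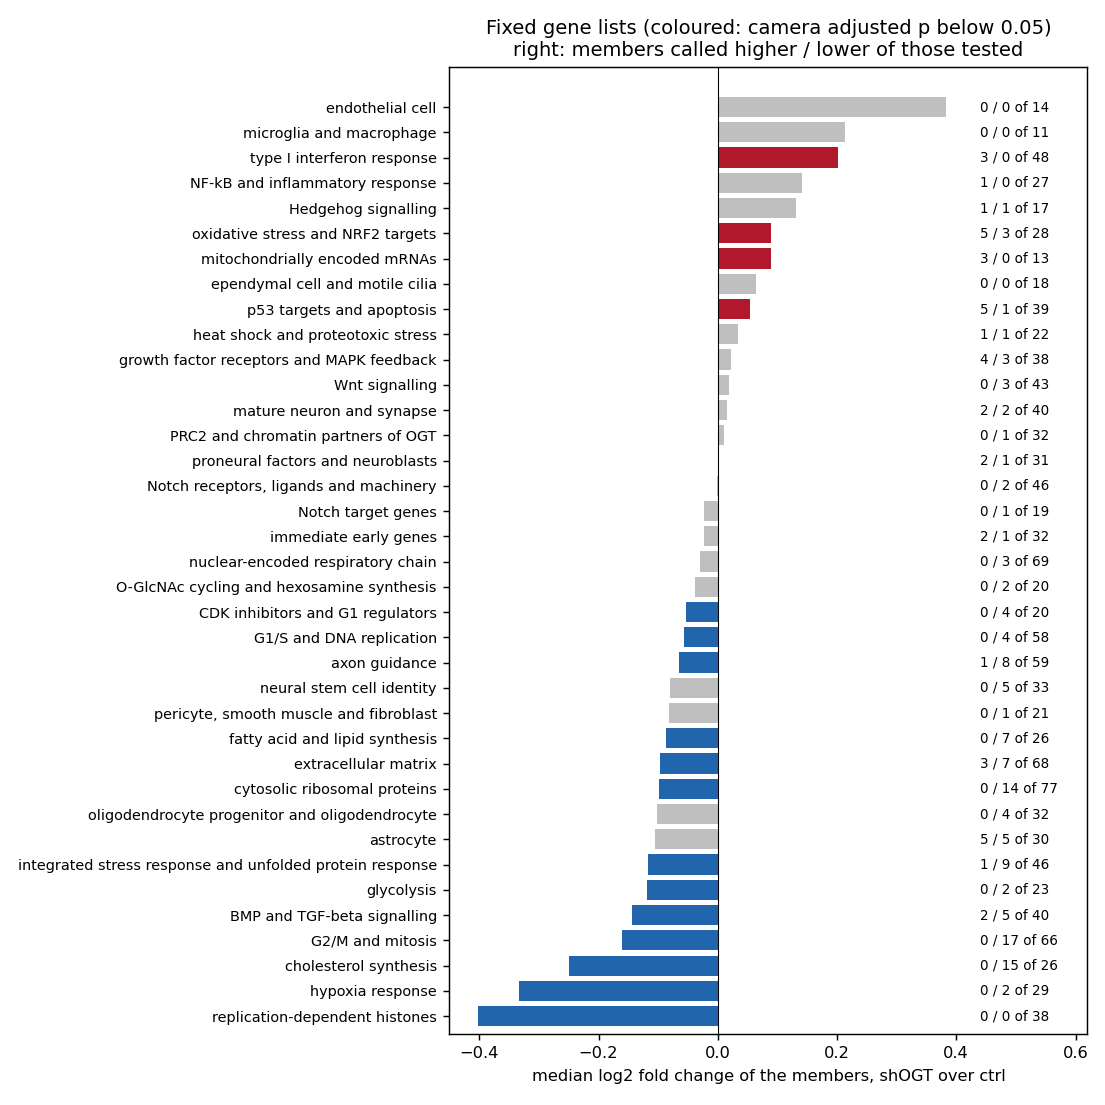
Median log2 fold change of shOGT over ctrl (x axis) of the tested members of each of the 37 gene lists (y axis); coloured bars passed camera with a preset correlation (4 up in red, 13 down in blue), grey bars did not, and the counts at the right give members called higher and lower of those tested. Cholesterol synthesis lies at -0.25 and G2/M at -0.16, whereas both Notch lists lie near 0.

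None of the lists of endothelial, microglial, mural or ependymal markers passed camera with all 4 libraries. Of 14 endothelial genes tested, 0 were called in limma or adjusted over the list alone; Tek measured 2.98 ± 1.40 in ctrl and 7.96 ± 0.737 in shOGT, and the list did not pass with all 4 libraries (adjusted p = 0.139) but passed without ctrl 2 (0.0252). Of 11 microglia and macrophage genes, 0 were called over all genes or over the list alone (adjusted p = 0.668), and Lyz2 measured 3.47 ± 3.50 and 6.96 ± 0.822. Of 21 genes of pericytes, smooth muscle and fibroblasts, 1 was lower, Col5a1 (-0.38, with GTACCC in the 3' UTR), as it was adjusted over the list alone (adjusted p for the list 0.342). Of 18 ependymal and motile cilia genes, 0 were called over all genes or over the list alone (adjusted p = 0.164), with Foxj1 at 589 ± 43.5 and 704 ± 38.6.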

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

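The minimum of 10, the rescaling to equal totals and the combinations with the minimum of 10 were chosen after seeing the data. The count of called genes (1060, with 427 higher and 633 lower) moved with the filter: 1819 (756 and 1063) at a minimum of 5 and 1955 (822 and 1133) at a minimum of 10. It was 634 (237 and 397) with a pseudocount of 0.1, 282 (102 and 180) at an adjusted p under 0.01, and 38 (22 and 16) with an absolute log2 fold change of at least 1. Limma made 0 calls with quantile normalization, with no filter and without the variance trend, where 3998, 4302 and 2763 genes had an unadjusted p under 0.05. The log2 fold change of Ogt was then -0.25, -0.26 and -0.26, with an adjusted p of 0.0936, 0.115 and 0.349. Over all settings the adjusted p of Ogt ran from 5.3e-08 to 0.349 and that of the Notch targets from 0.0447 to 0.556. With the minimum of 10 quantile normalization gave 1657 calls, so that its 0 calls went with the low genes that the minimum of 1 keeps. The fit without the variance trend still gave 0 calls at the minimum of 10. Other reasons for the 0 calls were not tested. Leaving out 1 library gave 0 to 0 genes in total, higher and lower, 9 to 15 lists, an Ogt change of -0.29 to -0.23 and a Notch target median of -0.06 to 0.003. The lone library of a group was then assumed to vary like the other group.

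At the minimum of 10 the prior degrees of freedom of limma were 14.8, against 7.39 at the minimum of 1, 2.36 with no filter and 2.27 with quantile normalization. Quantile normalization left 144 genes with no spread at all, and leaving out a library left 78 or 172. With the minimum of 10, leaving out ctrl 1 gave 275 genes (99 and 176) and leaving out ctrl 2 gave 329 (150 and 179) with 11 lists, with Ogt at -0.26 (adjusted p = 0.0635) and -0.25 (0.0679). Leaving out shOGT 1 gave 2335 (1017 and 1318), and shOGT 2 gave 2457 (991 and 1466), where the Notch targets passed at a median of -0.0227 (adjusted p = 0.0479). Quantile normalization with the minimum of 10 gave 1657 genes (799 higher, 858 lower). Without the trend it gave 0 (2891 at an unadjusted p under 0.05), with Ogt at -0.26 (adjusted p = 0.183).

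The numbers 1 and 2 are shared by the groups in the labels, which do not say that they pair cultures. Deviations from the group means did not correlate between same-numbered libraries (r = 0.0098 across 12982 genes, which are not independent replicates). No shared deviation was thus seen, but this cannot show whether same-numbered libraries came from a common culture. With the replicate block there were 2302 genes (1007 and 1295) and 20 lists (neural stem cell identity at an adjusted p of 0.000156 and the astrocyte and oligodendrocyte lists at 0.05 were added), and 2572 genes (1126 and 1446) with the minimum of 10. Of the 37 lists, 17 passed camera and 0 passed with an estimated correlation, a test with little power at 4 libraries. Fry passed 7: the Notch targets (median -0.0229, adjusted p = 0.0447), and ribosomal proteins, the stress response, interferon, matrix, NRF2 and heat shock (0.0438 each). With 8 HES, HEY and Nrarp genes alone the median was -0.04. Across the 19 settings other than these 2 set tests, 6 lists were called each time: G2/M, cholesterol, fatty acid, ribosomal protein, stress response and interferon. For the other 11 called lists the highest adjusted p was 0.237 (G1/S), 0.148 (CDK inhibitors), 0.0791 (p53), 0.0856 (NRF2), 0.741 (glycolysis), 0.281 (hypoxia), 0.215 (mitochondrial mRNAs), 0.19 (BMP), 0.0856 (matrix), 0.235 (axon guidance) and 0.183 (histones). Alternatives meant for count tables (another scaling, 2 other tests and a filter on CPM) were not run, since no count test was used. In the simulated libraries, where genes of similar level shared 1 spread, changes of log2 0.3 were recovered in 55.2% of genes of mean 100 or more. Lower genes were not changed there and depth was not varied.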

Other observations

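Among the sequence tests given here, GCTATC, GTACCC and GTGTCAC were chosen after all sequences of 6 to 8 bases had been scanned, and the tests of UTR length, GC content and expression were chosen after the result was seen. In BMP and TGF-beta signalling 2 of 40 rose and 5 fell (3 and 11 adjusted over the list alone): Bmp7 (-0.42 ± 0.05) and Fstl1 (-0.36) fell while Tgfbr2 (0.50) and Tgfb2 (0.34) rose. The 3' UTRs of Bmp7, Fstl1 and Tgfbr2 held GCTATC or GTACCC, and that of Tgfbr2 held GTGTCAC too. The list passed camera (median -0.14, adjusted p = 0.0211; 0.441 as the adjusted p with an estimated correlation), but not without ctrl 2 (0.0695) or shOGT 1 (0.0784), nor at a minimum of 10 (0.0547). Of 59 axon guidance genes, 8 fell, among them Nrp1 (-0.54) and Sema5b (-0.40), and Sema5a rose (0.64 ± 0.05), with 1 higher and 11 lower adjusted over the list alone. That list passed (median -0.06, adjusted p = 0.0184; 0.449 as the adjusted p with an estimated correlation), but not without ctrl 2 (0.0639) or shOGT 2 (median -0.02, adjusted p = 0.22). Without shOGT 1 the median was -0.11. Matrix genes were lower in 7 of 68 cases and higher in 3 (12 and 6 adjusted over the list alone). Ncan, the proteoglycan neurocan, fell from 17638 ± 187 to 10817 ± 498 (-0.71 ± 0.04, adjusted p = 0.000156), and Mmp15 (-0.47), Vcan (-0.45) and Timp2 (-0.34) fell as well. Ncan, Vcan, Timp2 and Sema5a held GCTATC or GTACCC, and Sema5b held GTGTCAC. That list's median was -0.10 (adjusted p = 0.00916; 0.374 as the adjusted p with an estimated correlation; 0.0856 without shOGT 2).

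The remaining lists did not pass camera. In growth factor and MAPK feedback 4 of 38 rose, among them Dusp6 (0.29) and Spred1 (0.26), and 3 fell, among them Erbb4 (-0.38; adjusted p for the list 0.439; 7 and 5 adjusted over the list alone). In Hedgehog signalling the receptor Ptch1 rose (0.34 ± 0.05) and Smo fell (-0.23 ± 0.05), the 2 called of 17 (0.347; 1 and 1 adjusted over the list alone). In Wnt signalling 3 of 43 fell, among them Fzd2 (-0.46) and Lrp5 (-0.32), and the list's median was 0.02 (0.07 without shOGT 1 and 0.05 without shOGT 2) and its mean -0.02 (0.68; 4 and 4 adjusted over the list alone). Rbbp7 (-0.18) was the 1 lower of 32 genes of PRC2 and chromatin partners (0.68; 1 and 2 adjusted over the list alone). Cryab rose (0.48) and Hspa4l fell (-0.32) of 22 heat shock genes (0.342; 4 and 1 adjusted over the list alone). Of 32 immediate early genes 2 rose, among them Klf4 (0.56), and Srf fell (-0.36), with a median of -0.02 that was 0.01 without ctrl 1, 0.003 without ctrl 2, -0.01 without shOGT 1 and -0.007 without shOGT 2, and a mean of 0.05 (0.876; 3 and 2 adjusted over the list alone). Erbb4, Smo, Hspa4l and Dusp6 held GCTATC or GTACCC in the 3' UTR, and Dusp6, Spred1, Ptch1 and Lrp5 held GTGTCAC.

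Short sequences in 3' UTRs went with the direction of change. Among 10780 expressed genes with an annotated 3' UTR, the sequence of 6 bases with the lowest score was GCTATC (z = -11.6), then GTACCC (-7.12), where 100 permutations of the fold changes reached -5.43 at the lowest. Scores, shifts and site differences used fold changes from which 3' UTR length, GC content and expression level had been taken out. Contrasts within a group reached -3.31 to 3.84. Genes lower in shOGT held GCTATC or GTACCC in 334 of 602 cases, where 187 were expected (Fisher's exact test, p = 5.1e-37). Genes higher in shOGT held GTGTCAC in 82 of 392 cases, where 44.9 were expected (Fisher's exact test, p = 4e-08). The 3 sequences were picked from the same fold changes, and UTR length was not a term in Fisher's test. Both p-values thus describe the overlap and do not test it. When the genes were split at random into 2 sets and each was searched alone, GCTATC came first both times, with a shift of -0.0612 ± 0.0076 and -0.0616 ± 0.0076 in the set not searched. GTGTCAC came first of the 7-base sequences in 1 of the 2 sets, with 0.0232 ± 0.0084 in the other; of the 6-base sequences TGTCAC came first in the same set, with 0.0090 ± 0.0054 in the other. The first of the rising sequences of the second set gave -0.0010 ± 0.0053 (TACAGA) and -0.0072 ± 0.0086 (ATGAGAG) in the other, and GTACCC had no such search of its own.

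Small RNAs made from the Ogt hairpin that pair through their seed with other transcripts are a candidate explanation for the lower genes with GCTATC or GTACCC. Genes with 2 or more sites lay below genes with 1 site by a difference of -0.0403 ± 0.0083 on the log2 scale, as such repression needs. This difference comes from the same genes and fold changes that chose the sequences. Any other cause that acts through these sites would give it too, so that it cannot single out the hairpin. UTR length, GC content and expression level were already terms of the scan that chose the sequences. The shift of -0.0520 ± 0.0041 with them thus cannot test them. For GCTATC, the shifts with these terms in the sets not searched, -0.0612 ± 0.0076 and -0.0616 ± 0.0076, argue against them as the whole cause. The weaker of 2 separate library pairs gave -0.0497 ± 0.0046, though the sequences had been chosen from all 4 libraries. In each pair scanned alone GCTATC came first (z = -11.4 and -10.2), which argues against a single library for GCTATC. Second came CTATCA in shOGT 1 against ctrl 1 (-6.97) and GTACCC in shOGT 2 against ctrl 2 (-6.78). The shift of GTACCC in shOGT 1 against ctrl 1 was -0.0360 ± 0.0055. The reverse complements gave -0.0019 ± 0.0040, and coding sequences -0.0233 ± 0.0038. It stays open whether the hairpin has these seeds, as its sequence is not given in the sources used here; microRNAs of the cells and an effect of the lower Ogt itself on these transcripts were not tested.

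For the higher genes with GTGTCAC, the same kind of small RNA from the scrambled hairpin in ctrl is a candidate explanation. Genes with 2 or more sites lay above genes with 1 site by 0.0377 ± 0.0143. This difference too comes from the fold changes that chose the sequence, and cannot single out the scrambled hairpin. Length, GC content and expression level were already terms of the scan that chose GTGTCAC. The shift of 0.0384 ± 0.0059 with them thus cannot test them. In the set not searched the shift was 0.0232 ± 0.0084. Because GTGTCAC came first in 1 of the 2 sets and not in the other, and TGTCAC lay within 2 SE of 0 in the set not searched, this pattern rests on less than that of GCTATC. An effect of the lower Ogt on these genes stays open, as untested.

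For the gene list calls, genes that held any of the 3 sequences in the 3' UTR and a trend in transcript length and GC content were weighed. Genes with a sequence in the coding sequence alone stayed in, although coding sites of GCTATC or GTACCC gave a shift of -0.0233 ± 0.0038. Without the genes that held a sequence in the 3' UTR, 16568 were tested, with 118 higher and 138 lower, against 427 and 633 of 21829. The fit and the adjustment were redone on the smaller set, which can itself lower the number of calls. The 13 mitochondrially encoded mRNAs lost no member and kept a median of 0.09, yet 1 was called higher instead of 3. The falls in called genes and called list members thus cannot be credited to the removed genes alone. Then 13 of the 17 called lists were past the threshold in the same direction, and neural stem cell identity (adjusted p = 0.0489), NF-kB (0.019) and the respiratory chain (0.0471) were gained. The calls of glycolysis, BMP and TGF-beta signalling and axon guidance ended at medians of -0.11 (SD 0.29), -0.14 (0.47) and -0.06 (0.23) over 16, 18 and 30 genes. With all genes these were -0.12 (0.34), -0.14 (0.40) and -0.06 (0.29) over 23, 40 and 59. Both fewer genes and fewer called members went with the loss. Called lower members went from 2, 5 and 8 to 0, 0 and 1, and higher members from 0, 2 and 1 to 0, 1 and 0. The histones moved from a median of -0.40 (0.73) to -0.27 (0.74). With the trend taken out of each library 17 of 17 were past it, the neural stem cell (0.0136), oligodendrocyte (0.0449) and respiratory chain lists (0.0234) were gained, and 454 genes were higher and 980 lower, against 427 and 633. These values argue against the sequences in 3' UTRs, and against the trend, as the whole cause of the list calls. The sequences in coding regions, indirect effects of genes that held the sequences, and the lower Ogt itself stay open and may contribute.

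The protein-coding Ogt transcript with the longest 3' UTR holds GCTATC at 101663483 to 101663488 and GTACCC at 101668093 to 101668098 of chromosome X on GRCm38, both in the coding sequence. A sequence of 6 bases is common by chance in a transcript of this length, so that this decides nothing about the hairpin.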
